A study of Drosophila melanogaster with 23 samples.

How the data were processed

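The series measured gene expression in adult males of 8 strains of Drosophila melanogaster on 23 spotted 2-colour cDNA microarrays. Per the labels, flies were reared at 25 °C and adult males were kept apart from females for 3 to 4 days. RNA was extracted from 8 to 12 flies at a time, and the extractions of a strain were pooled into a single RNA sample. From 2 µg of poly-A RNA, amino-allyl cDNA was made and coupled to cyanine 3 or cyanine 5. Because each strain had 1 RNA pool, the arrays of a strain are technical repeats, and the p-values of the F test, of single strains and of pairs measure the spread between arrays, not between flies or rearings.

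The deposited values are log ratios of the 2 channels of an array, in 1 table of 6101 features by 23 arrays. The scanner, the spot filter and the normalization are not given in the sources used here. The deposited log ratios carry no stated base, and were read here as log10 ratios. Base 10 is likely, since the largest deposited value of 1.56 would be a ratio of 36.4 as log10 and of only 2.95 as log2, and the arrays of a strain against itself would scatter by only 3.02% and 3.68% as log2, against 10.4% and 12.8% as log10. All folds below rest on this reading. The median of an array lay between -0.0473 and -0.00352 on the deposited scale for the arrays of different strains, so the values were close to 0 but not exactly centred. Which channel was the numerator is not stated either. Arrays of the same pair of strains with the channels exchanged were anticorrelated in all 8 such pairs (across features, r from -0.809 to -0.285), so the ratios ran in 1 fixed channel order. The 2 genes chosen beforehand to settle the direction, Cyp6g1 and desat2, are not among the features named here. By the rule set for that case, no strain is called higher or lower: sizes are given, and strains are said to lie on the same side or on opposite sides of the mean of the 8 strains. A further attempt, chosen after the data were seen, related missing spots to the fitted levels in 275 features and did not settle the direction (50.5% positive, permutation p = 0.928).

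Of the 6101 features, 1084 had no value on any array, and an array gave values for 3272 to 4987 features. No spot intensities were used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision. Gene names came from the platform annotation supplied with the values: 1943 features had 1 gene symbol, 67 had several and 4091 had none here. All 1943 Entrez identifiers matched the Release 6 gene table, which changed no symbol and served only for chromosome arms and for which genes are neighbours. Features with several genes or none were counted but not named. Each column of the table belongs to a known sample.

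Values were multiplied to the log2 scale and each array was centred on its median. A dye offset per feature was estimated from the 8 channel-exchanged pairs and subtracted. Arrays of 1 pair were turned the same way and averaged, which gave 13 pairs of strains, 8 of them from 2 arrays and 5 from 1 array. Strain levels were fitted to the 13 pair values by least squares weighted by the number of arrays, and the variances were moderated with limma 3.58.1 in R 4.3.3. Features entered with at least 10 of the 13 pairs measured and all 8 strains estimable. A further condition of at least 3 complete channel-exchanged pairs, needed for the dye offset, was added after the design had been set. This left 4841 features, among them 1503 named ones for 1409 genes. The Benjamini-Hochberg adjusted p had to be under 0.05, within each comparison. Strain deviations are relative to the mean of the 8 strains, or of the other 7 where stated.

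For the comparison of origins, the 8 strain estimates entered limma as 4 Zimbabwe strains against 4 others. Distances between strains were root mean square log2 differences over features, tested by an exact permutation of origin over the 35 splits of the 8 strains. Of 16 gene lists fixed before the data were examined, the 5 with at least 4 measured genes were tested: the median SD of strain levels was set against 10000 random lists of the same size matched on residual SD, with features of a gene averaged. Shifts of lists used limma's camera with the preset correlation of 0.01 and with the estimated one. X-linked genes and genes on 2L, 2R, 3L and 3R, called autosomal here, were compared by a permutation test with 100000 resamples. Where a gene had several features, the one measured on most arrays, then with the lowest residual SD, stood for it in all other results. Of 65 such genes, 47 had features that all passed or all missed the F test, and the median correlation between strain profiles of the features of a gene was only 0.41.

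Genes named in the text were chosen by a rule set before the data were examined: the 20 named genes with the largest range among strains past the F test; per strain the 2 largest differences on each side against the other 7; all named genes past the comparison of origins; and per list up to 4 members past the F test. The fit was tested on simulated data with the real pattern of arrays and missing values. Among 4841 features, it recovered 2 of 67 simulated to differ 1.25-fold in 1 strain, 38 of 67 simulated to differ 1.5-fold and 64 of 66 simulated to differ 2-fold, with 6.31% false calls. In a separate simulation, the comparison of 4 with 4 strains recovered 96 of 100 features simulated at 2-fold, with 3.92% false calls. That simulation drew independent strain values directly, without arrays or missing values. Its shares therefore do not cover unequal precision of the strains or errors that strains share through arrays. The errors simulated for the fit were independent between arrays, whereas real arrays with a shared title stem deviated together. The 6.31% therefore does not cover errors shared by such arrays. Alternatives changed the dye term, the averaging, the centring, the scaling, the weights, the feature filter, the variance prior and the array left out, and treated the shared stem of array titles as a random block. Arrays of a strain against itself stayed out of the fit of strain levels and measured noise.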

Results

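Expression was compared directly between strains of Drosophila melanogaster on 2-colour arrays, to ask how much gene expression varies within the species. The strains were 4 from Zimbabwe (Zimbabwe2, Zimbabwe29, Zimbabwe30 and Zimbabwe53) and 4 others: Canton S and Oregon R, which are common laboratory stocks, Hikone R and St Louis. Of 23 arrays, 21 carried different strains in the 2 channels and 2 carried the same strain in both. Canton S was on 11 of the 21 arrays and Zimbabwe53 on 9. Oregon R and Zimbabwe30 were on 5 each, and Hikone R, St Louis, Zimbabwe2 and Zimbabwe29 on 3 each. Values were measured for 3272 to 4987 features per array. Each strain had 1 pooled RNA, so errors and p-values of single strains and pairs cover the spread between arrays only. The comparison of origins uses the spread between strains, and its distances permute strains, while the tests of gene lists and of the X set genes against other genes. Folds assume that the deposited ratios are log10, and which strain of a pair was higher is not settled.

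Arrays of a strain against itself set the noise. The SD of log2 ratios was 0.17 for Canton S against itself (4341 features) and 0.14 for Zimbabwe53 against itself (4216 features). It ranged from 0.28 to 0.52 over the 21 arrays of different strains, with a median of 0.39. Ratios beyond 1.5-fold made up 1.27% and 0.617% of features on the arrays of a strain against itself and 3.71% to 17.1% on the others. With 2 arrays of 2 strains in the first group, no test was made.

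**Figure D1:**
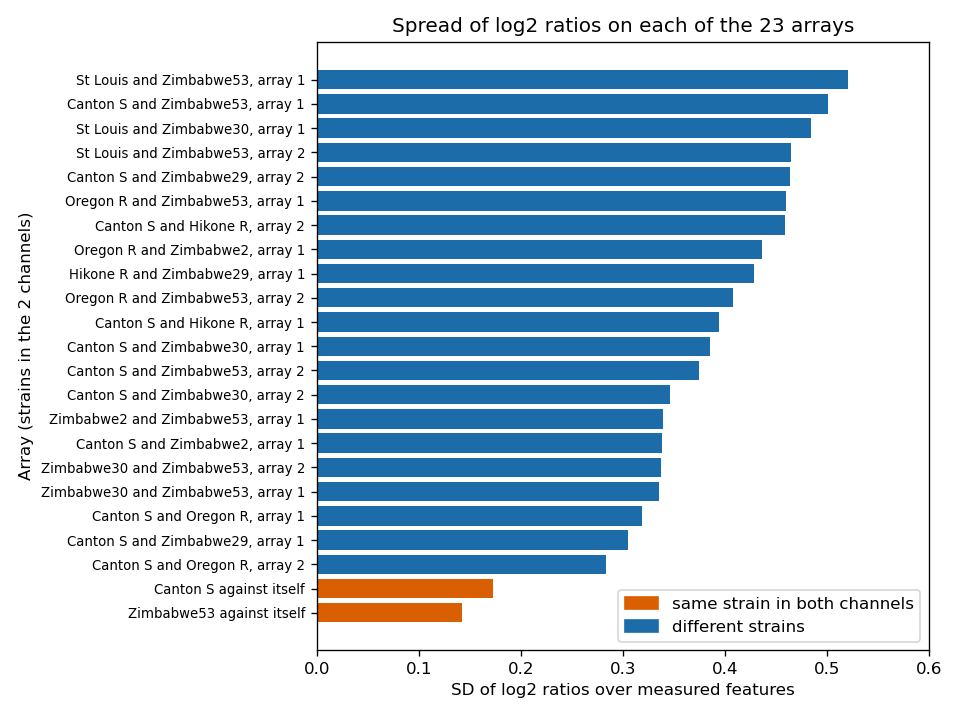
Bars give the SD of log2 ratios over the measured features of each of the 23 arrays, in log2 units. The 2 arrays with the same strain in both channels, at 0.14 and 0.17, lie below all 21 arrays of different strains, the lowest of which is at 0.28.

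The first comparison asked which genes differed among the 8 strains. The largest difference of a named gene was in CG5953 (Entrez 34985, arm 2L), which differed 35.1-fold between St Louis and Zimbabwe29 (log2 5.14 ± 0.28 SE, 21 arrays). Cpr72Ec, a cuticular protein gene on 3L, differed 15.9-fold between Zimbabwe30 and St Louis (log2 3.99 ± 0.22 SE, 19 arrays), and CG4757 on 3R differed 11.3-fold between St Louis and Zimbabwe53 (SE 0.11 log2, 20 arrays). All 4 Zimbabwe strains lay on the opposite side of the other 4 in CG5953, but this gene did not pass the comparison of origins described below. The next genes were vanin-like on the X, 5.49-fold between Canton S and St Louis, and mag, a gut lipase, 4.52-fold between Zimbabwe2 and Oregon R. Adjusted p-values of the moderated F test in limma were 4.9e-10 for CG5953, 7.8e-09 for Cpr72Ec, 5.4e-11 for CG4757, 1.7e-08 for vanin-like and 1.6e-08 for mag.

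The 20 named genes with the largest range included several enzymes. Mipp1, an inositol polyphosphate phosphatase, differed 4.41-fold, NT5E-2, a 5' nucleotidase, 4.19-fold, Sqor, which oxidises sulfide in mitochondria, 3.22-fold, and Glyp, glycogen phosphorylase, 3.06-fold between their extreme strains. The proteases and protease relatives yip7 and sphe differed 4.16-fold and 2.80-fold. The detoxification genes Cyp12d1-p, a cytochrome P450, and Ugt35A1, a UDP-glycosyltransferase, differed 3.66-fold and 3.04-fold. Prosbeta4R2, a proteasome subunit relative of the testis, differed 3.02-fold. The remaining genes of the 20 were CG12129 (4.49-fold), cDIP (4.27-fold), CG5966 (3.38-fold), CG13325 (2.98-fold), CG32444 (2.92-fold) and Gem3, a helicase of spliceosome assembly (2.83-fold). A near-identical copy of Cyp12d1-p lies in some genomes of the species, and a printed cDNA cannot tell such copies apart.

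**Figure D2:**
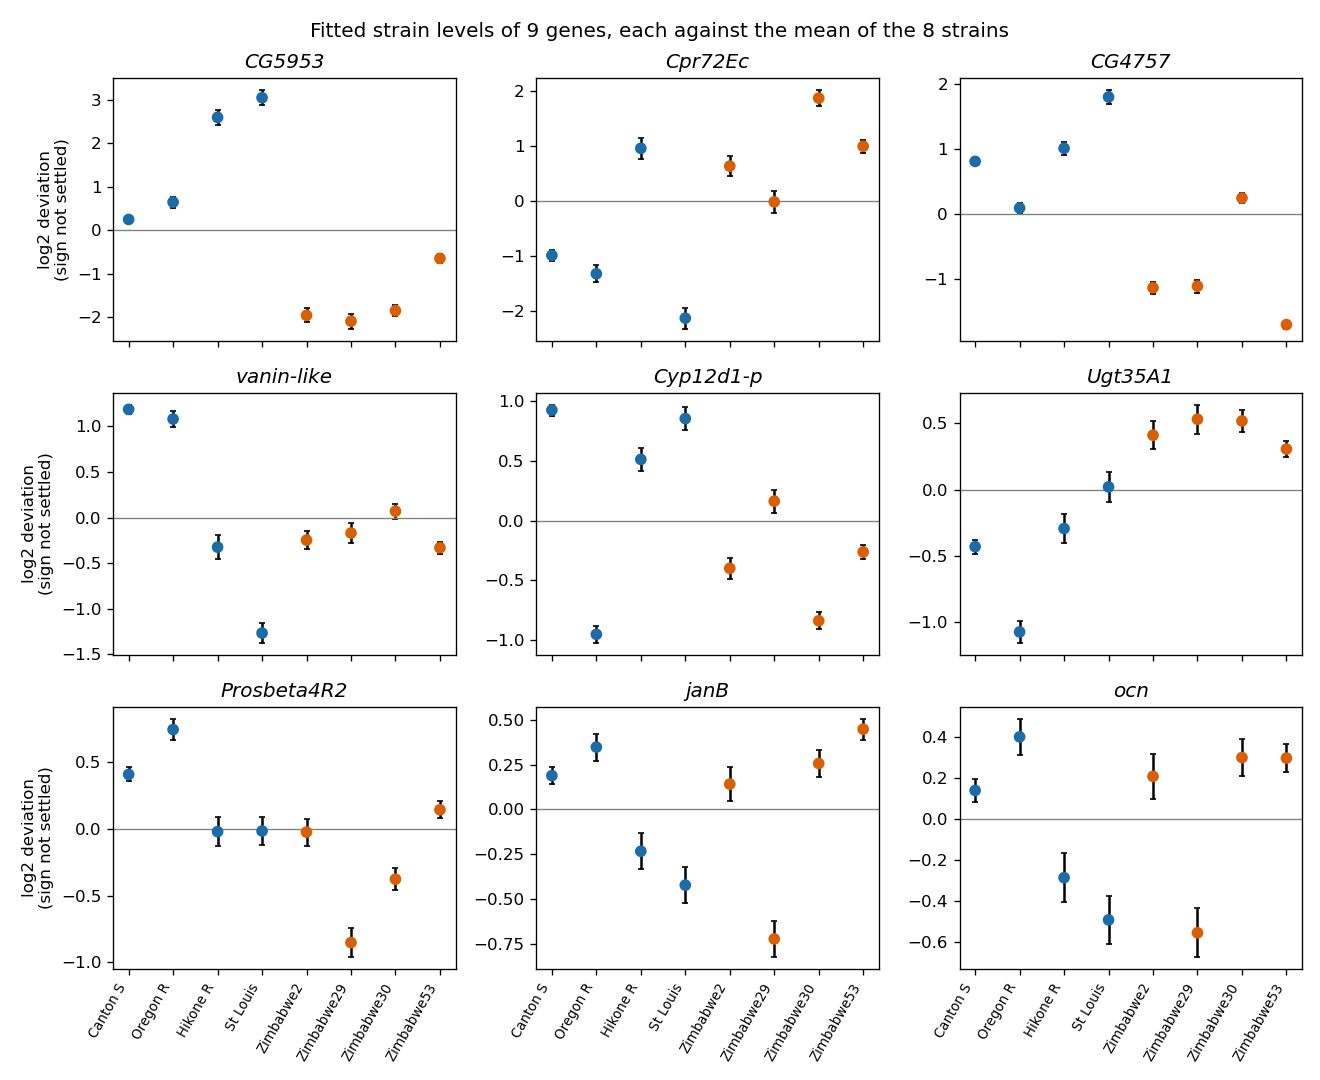
Points give the fitted level of each strain against the mean of the 8 strains, in log2 units, for 9 genes, with bars of 1 SE; blue marks Canton S, Oregon R, Hikone R and St Louis, orange the 4 Zimbabwe strains, and the sign of the axis is not settled. CG5953 places the 2 origins on opposite sides of the mean but did not pass the comparison of origins. Both janB and ocn place Zimbabwe29 and St Louis together on 1 side.

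In total, 2187 of 4841 features (45.2%) differed among strains in the moderated F test of limma. Among named genes the count was 543 of 1409 (38.5%), and 73 of them differed beyond 2-fold, 10 beyond 4-fold and 3 beyond 8-fold. The median difference between extreme strains of the 2187 features was 1.61-fold, with quartiles of 1.45 and 1.89. Beyond 8-fold lay 47 features, but 31 of these were in the last 2 grid rows of the print blocks. The strain profiles of these 31 were nearly alike (lowest pairwise r = 0.910 across the 8 strains). They have no gene name here, so whether the same DNA was printed repeatedly is not known. With only the features complete on all arrays of different strains, 1081 features passed, or 62.6% of those tested.

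The gene lists fixed beforehand were examined next, but few of their members were measured. The testis and spermatogenesis list had 7 of 73 listed names and the muscle list 5 of 28. The results speak for the measured genes, not for whole kinds of gene. Of 7 measured genes of the testis and spermatogenesis list, 5 passed the F test (6 when adjusted over the list alone). They were Prosbeta4R2, janB (2.25-fold), Hsp60B, a testis chaperonin (1.97-fold), ocn (1.94-fold) and Cdlc2, a dynein light chain (1.65-fold). ctp, another dynein light chain, and heph, an RNA-binding protein, did not pass (adjusted p = 0.077 and 0.372). The median SD among strains of the list was 0.37 log2, 2.27 times that of matched random lists (adjusted permutation p = 0.0015). Random lists draw genes independently, whereas the members of this list vary together (estimated correlation 0.220). The permutation p-values of this list may therefore be too small. Cdlc2, ctp and heph are not restricted to the testis; without them the ratio was 2.35 (adjusted permutation p = 0.0090). janB and ocn are neighbours in 1 cluster of related genes, and without ocn the ratio was 1.89 (adjusted permutation p = 0.0125).

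Of 8 detoxification enzymes, 6 passed the F test (7 when adjusted over the list alone). Besides Cyp12d1-p and Ugt35A1 these were GstE12 and GstE13, glutathione S-transferases (2.67-fold and 1.82-fold), the cytochrome P450 gene Cyp4ac1 (2.20-fold) and Ugt50B3 (1.38-fold). Cyp6u1 and Cyp4g15 did not pass (adjusted p = 0.060 and 0.325). The median SD of the list was 0.31 log2, 2.01 times that of matched random lists (adjusted permutation p = 0.0015). Muscle structure genes had 3 of 5 members past the F test (3 adjusted over the list alone): Prm, paramyosin (2.22-fold), Strn-Mlck (1.79-fold) and up, troponin T (1.45-fold). Of 4 cytoplasmic ribosomal protein genes, RpS12 (1.64-fold), RpL32 (1.41-fold) and RpS10a (1.38-fold) passed (3 adjusted over the list alone). The median SD of neither list differed from that of random lists (ratio 1.24, adjusted permutation p = 0.466, and ratio 1.13, adjusted permutation p = 0.627). Of 5 proteasome genes, 1 passed, Rpn1 (1.51-fold; 1 adjusted over the list alone). The ratio of the proteasome list was 0.650, with an adjusted permutation p of 0.0657, and it passed with 1 feature per gene (ratio 0.638, adjusted permutation p = 0.046). It also passed without the replicate 1 array of Canton S and Zimbabwe53 (ratio 0.630), of Canton S and Hikone R (0.597) or of Canton S and Zimbabwe30 (0.612), or the replicate 2 array of Zimbabwe30 and Zimbabwe53 (0.608). It rose to 0.787 without the dye offset (adjusted permutation p = 0.394), to 0.793 with the title stem as a block (adjusted permutation p = 0.395) and to 0.905 without the array of Hikone R and Zimbabwe29 (adjusted permutation p = 0.858). RpS12 no longer passed when any 1 of 6 arrays was left out (highest adjusted p = 0.081, without the replicate 2 array of Canton S and Zimbabwe30).

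**Figure D3:**
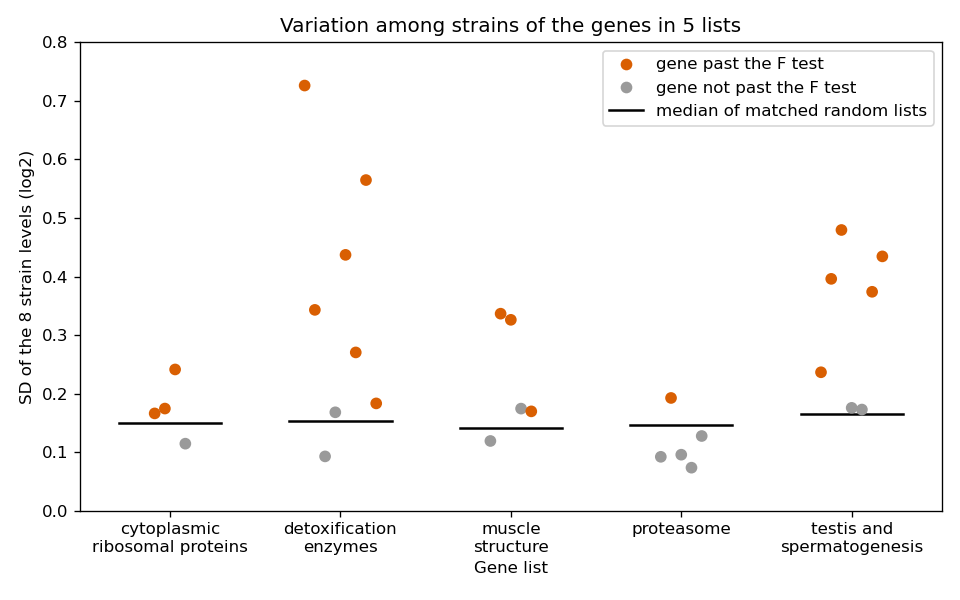
Each point is a gene, placed by the SD of its 8 fitted strain levels in log2 units, and the black lines are the medians of random lists matched on residual SD. In the detoxification and testis lists, 6 of 8 and 5 of 7 genes passed the F test, and all of these lie above the line.

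Other lists had too few measured genes for a test. In both measured digestive genes, mag and yip7, the strains differed. Of central metabolism, all 3 measured genes passed: Got2, an aspartate aminotransferase (2.55-fold), fbp, fructose bisphosphatase (1.75-fold) and Treh, trehalase (1.47-fold). The single measured odorant-binding gene, Obp19d, differed 2.01-fold, and the single heat shock gene, Hsp60B, is named above. Of 2 genes each, the eye list had Galphaq (1.47-fold) and rdgA (1.33-fold) past the test, oxidative phosphorylation had ND-51 (2.01-fold) but not COX7C (adjusted p = 0.525), cuticular hydrocarbon synthesis had FASN1, a fatty acid synthase (1.89-fold), but not bond (adjusted p = 0.239), and the clock list had Pdp1 (1.45-fold) but not cwo (adjusted p = 0.0565; both passed when adjusted over the list alone). No gene of the accessory gland, ovary or immune lists was among the named features of the fit. Galphaq was no longer past the threshold without the dye offset (adjusted p = 0.105), rdgA with equal weights (adjusted p = 0.0703) or without any 1 of 8 arrays (highest adjusted p = 0.120), and fbp without either of 2 arrays (highest adjusted p = 0.0683).

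The next comparison set each strain against the mean of the other 7. Zimbabwe53 differed in 1269 features and Canton S in 922, the strains with the most arrays. Oregon R differed in 599, Zimbabwe30 in 574, Hikone R in 527, Zimbabwe29 in 432, Zimbabwe2 in 314 and St Louis in 301. Beyond 2-fold, the numbers ran from 20 in Zimbabwe29 to 78 in Hikone R, but much of that range came from features in the last 2 grid rows of the print blocks. Without those rows the numbers ran from 18 in Zimbabwe53 and 20 in Zimbabwe29 to 36 in Oregon R and 45 in Hikone R. The median SE was 0.060 log2 for Canton S and 0.074 for Zimbabwe53, but 0.12 to 0.13 for the strains on 3 arrays, so the counts follow the precision as well as the strains. The calls fell about evenly on both sides: the larger side held 50.7% of them in Zimbabwe30 and 58.6% in Zimbabwe2. In Zimbabwe53 that side held 51.7%, and 62.8% when arrays were not centred.

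St Louis stood apart in CG5953 by 11.2-fold (log2 3.48 ± 0.19 SE) and in CG4757 by 4.15-fold, and on the opposite side in Cpr72Ec by 5.38-fold and CG12129 by 3.61-fold. Hikone R shared the side of St Louis in CG5953 (7.81-fold), and also differed in Sqor (2.64-fold) and, on the opposite side, CG14502 (1.78-fold) and Acat1 (1.78-fold). Zimbabwe2, Zimbabwe29 and Zimbabwe30 lay on the opposite side of St Louis in CG5953, by 4.70-fold, 5.23-fold and 4.32-fold. Zimbabwe53 differed in Mipp1 (3.23-fold) and, on the opposite side, in CG4757 (3.85-fold) and cDIP (2.68-fold). Zimbabwe30 differed in Cpr72Ec (4.38-fold), Rabex-5 (1.81-fold) and, on the opposite side, GstE12 (2.08-fold). Zimbabwe29 differed in Glyp (2.23-fold) and CG32444 (2.22-fold), and Zimbabwe2 in mag (2.34-fold) and CG31759 (1.67-fold). Zimbabwe29 and Zimbabwe2 also lay on the opposite side of St Louis in CG4757, by 2.41-fold and 2.46-fold. Zimbabwe53 lay on the side of Zimbabwe30 in Cpr72Ec, by 2.19-fold. Canton S and Oregon R lay on the same side in vanin-like, by 2.56-fold and 2.36-fold, and in Cpr72Ec, by 2.18-fold and 2.84-fold. Canton S further differed in Cyp12d1-p (2.08-fold) and rtet (2.07-fold), and Oregon R in NT5E-2 (3.36-fold) and dpp, a BMP ligand (1.85-fold). CG14502 was past the threshold neither without the dye offset (adjusted p = 0.0561) nor without the array of Hikone R and Zimbabwe29 (adjusted p = 0.0776). CG31759 failed without the array of Zimbabwe2 and Zimbabwe53 (adjusted p = 0.0618), and dpp without the array of Canton S and Zimbabwe2 (adjusted p = 0.0632).

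The counts of strains on few arrays rested on single arrays. Zimbabwe2 fell to 147 features without its array with Canton S, to 187 without that with Zimbabwe53 and to 39.2% of its count without that with Oregon R. Zimbabwe29 fell to 164 without its array with Hikone R, to 219 without the replicate 2 array with Canton S and to 283 without the replicate 2 array of Canton S and Zimbabwe53. St Louis fell to 148 and Zimbabwe30 to 320 without the array that joins them, and Zimbabwe30 to 312 without its replicate 2 array with Canton S. Hikone R fell to 329 without the replicate 1 array with Canton S, and Oregon R to 397 without its array with Zimbabwe2. Fitting single arrays without averaging pairs raised St Louis to 444 and Zimbabwe2 to 426. On top of that, the title stem as a block gave 572 and 473, and a dye term per title prefix gave 477 and 445. From averaged pairs, Zimbabwe2 reached 506 with scaled arrays, and Oregon R 915 and St Louis 486 with centred print blocks.

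Some lists were shifted against other genes in some strains, with part of their members called. The testis genes lay on 1 side in Zimbabwe29 (median log2 size 0.48, 4 of 7 members called, all on that side; adjusted p = 2.7e-06 in camera). St Louis had a median of 0.40 on the same side (adjusted p = 0.0193). Oregon R (median 0.40, 4 called) and Zimbabwe53 (median 0.34, 4 called) lay on the opposite side, with adjusted p = 0.0106 and 0.0149. These sides did not change with other centrings or scalings. With the correlation estimated from the data (0.220 for this list), Zimbabwe29 kept its call (adjusted p = 0.0053), while the shift was no longer past the threshold in Oregon R (adjusted p = 0.140), St Louis (adjusted p = 0.172) or Zimbabwe53 (adjusted p = 0.172). The detoxification list was shifted in Oregon R (median 0.18, 2 of 8 called; adjusted p = 8.5e-06) and, on the opposite side, in St Louis (median 0.14, 1 called; adjusted p = 0.0288). In Zimbabwe30 it passed as well (adjusted p = 0.0197), but the median was only 0.032 and its 3 called members lay on both sides. The muscle list was shifted in Zimbabwe2 (median 0.25, 2 of 5 called; adjusted p = 0.0116). With an estimated correlation the muscle call held (adjusted p = 0.0342, correlation 0.0825). The estimated correlation of the detoxification list was 0, below the preset 0.01, which lowers its unadjusted p-values and makes this no stricter test. Its 3 calls held, with adjusted p = 6.8e-06 in Oregon R, 0.0342 in St Louis and 0.0329 in Zimbabwe30 in camera. In all, 8 of 45 combinations of list and comparison passed, and 5 with the estimated correlation or without the array of St Louis and Zimbabwe30.

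Pairs of strains were compared next. Over the 28 pairs the median count of differing features was 599. It was lowest for Hikone R and St Louis, at 145, and highest for St Louis and Zimbabwe53, at 1225. Canton S and Zimbabwe53, the most often hybridised strains, differed in 1189. The median count was 397.5 for the 6 pairs among the other strains, 299 for the 6 pairs among Zimbabwe strains and 663 for the 16 pairs between origins. Such counts follow the precision as well as the strains, and the kinds of pair were not matched for it. The median SE was 0.18 log2 for Hikone R and St Louis, which shared no array. It was 0.11 log2 for St Louis and Zimbabwe53, which shared 2. Restricting the features to complete ones lowered the median count over the 28 pairs to 322.5.

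**Figure D4:**
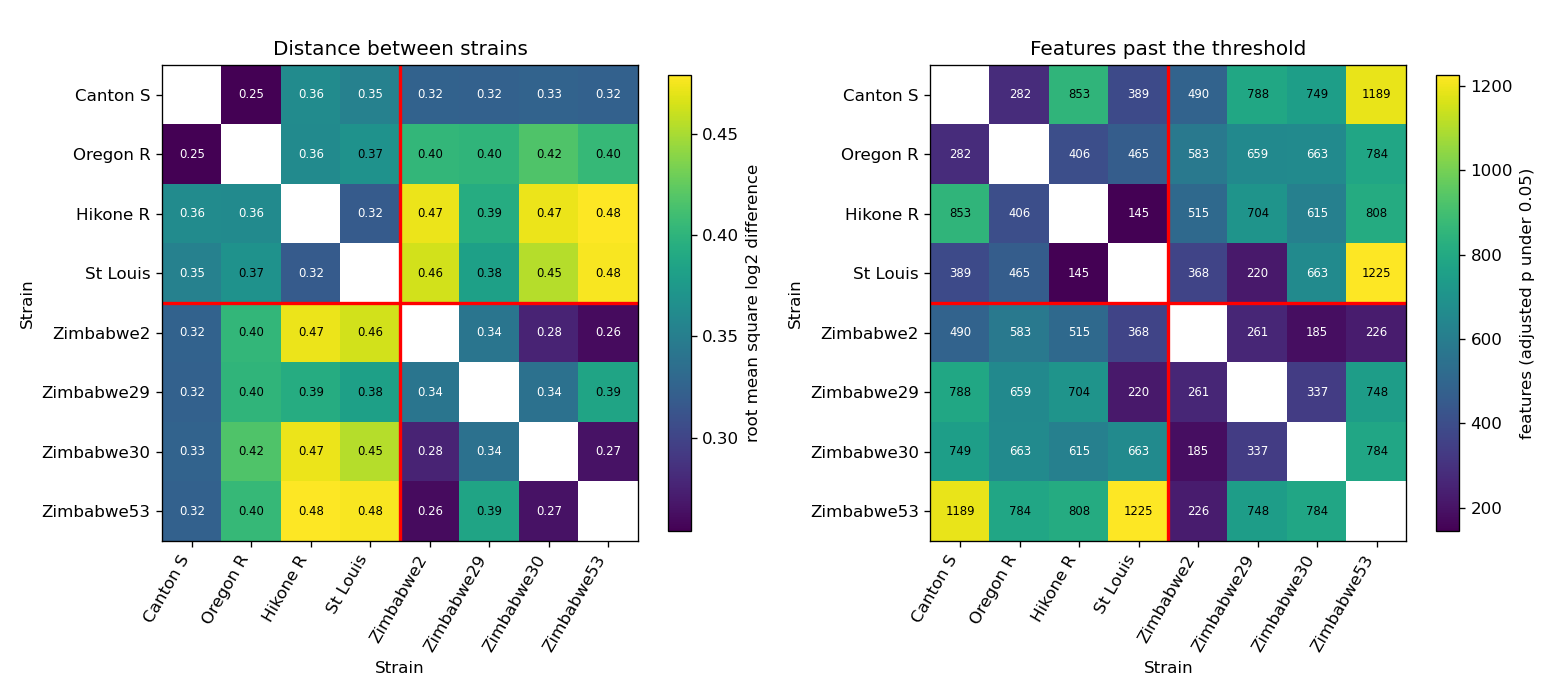
The left panel gives the root mean square log2 difference over 4841 features for each pair of strains, the right panel the number of features past the threshold for that pair; red lines part the 4 other strains from the 4 Zimbabwe strains. Distances reach 0.48 between origins, for Zimbabwe53 against Hikone R and St Louis (0.38 and 0.36 without the last 2 grid rows of the print blocks), and fall to 0.25 for Canton S and Oregon R (0.22 without them).

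The comparison of origins asked whether the Zimbabwe strains differ as a group from the other 4. With the strain as the unit, 12 features passed, 6 on each side, with folds from 1.45 to 7.33. Of these, 2 were named genes: CG13360 on the X (1.61-fold; log2 0.69 ± 0.10 SE) and CG7778 on 2L, on the opposite side (1.47-fold; log2 0.55 ± 0.08 SE), each with an adjusted p of 0.0481 in limma for 4 against 4 strains. Both calls were lost when arrays were scaled to 1 spread (adjusted p = 0.0616 and 0.0697) or print blocks were centred (adjusted p = 0.0567 and 0.0551), although the sizes changed little: log2 0.69 and 0.68 for CG13360, and log2 -0.57 under both settings for CG7778, signed as opposite sides. Both also ended without any 1 of 7 arrays: replicate 1 of Canton S with Hikone R or Oregon R, replicate 2 of Canton S with Zimbabwe29 or Zimbabwe30, replicate 2 of St Louis and Zimbabwe53, and the arrays of Hikone R and Zimbabwe29 and of Zimbabwe2 and Zimbabwe53 (highest adjusted p = 0.0698 and 0.0860). CG7778 ended as well without replicate 1 of Canton S with Zimbabwe29 or Zimbabwe53, or the array of St Louis and Zimbabwe30. Among 4841 features, 540 had an unadjusted p under 0.05. In 322 features (6.65%), 90 of them named genes, the 2 origins did not overlap, against 2.86% by chance. Of the other splits of the 8 strains into 4 and 4, however, 2 gave more such features, 349 and 368, so this count alone does not tie the excess to origin. The count of 12 fell to 2 with scaled arrays or centred print blocks, and to 2 or 3 without any 1 of the 7 arrays named for both genes, or 6 without that of St Louis and Zimbabwe30. It was 0 without Zimbabwe2 or Zimbabwe30, 1 without Hikone R, 3 without Oregon R, 6 without St Louis, 7 without Zimbabwe53, 32 without Zimbabwe29 and 58 without Canton S, and 19 without the last 2 grid rows. With the error between arrays in place of that between strains, 1365 features passed.

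On average, strains of different origin were farther apart than strains of 1 origin, but not in every pair. With all grid rows, Canton S was nearer to every Zimbabwe strain (0.32 to 0.33 log2) than to Hikone R (0.36) or St Louis (0.35). Without the last 2 grid rows of the print blocks this no longer held. St Louis (0.3024) was then nearer to Canton S than Zimbabwe2 (0.3107), Zimbabwe29 (0.3248) and Zimbabwe30 (0.3055) were, though not Zimbabwe53 (0.2979). Hikone R (0.3255) was about as far as Zimbabwe29. The nearest strain to Canton S was Oregon R (0.25, and 0.22 without those rows). Zimbabwe29 was nearer to Canton S (0.32) than to Zimbabwe53 (0.39). The mean distance was 0.41 log2 between origins, 0.31 among Zimbabwe strains and 0.34 among the others, and the difference between and within origins was 0.084 (exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow). Without the last 2 grid rows of each print block, the difference was 0.043, with the same smallest possible p. The distance among Zimbabwe strains did not differ from that among the others (exact permutation p = 0.629).

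Genes on the X were compared with autosomal genes. Of 252 named X-linked genes, 81 (32.1%) differed among strains, against 457 of 1139 genes on 2L, 2R, 3L and 3R (40.1%; Fisher's exact p = 0.0185). Chromosome 4 was left out of the autosomal group. The share was 43.1% on 2L, 40% on 2R, 43.0% on 3L, 35.8% on 3R and 29.4% (5 of 17 genes) on chromosome 4. The median SD of strain levels was 0.139 log2 on the X and 0.150 on the autosomes (permutation p = 0.0312, two-sided). That difference of -0.0109 no longer passed with scaled arrays (permutation p = 0.114), with the title stem as a block (permutation p = 0.0565) or without the last 2 grid rows (permutation p = 0.0742). It ended without any 1 of 11 of the 21 arrays, with permutation p from 0.0519 to 0.221: both arrays of Canton S with Zimbabwe53 or Zimbabwe29, replicate 1 of Canton S and Zimbabwe30, of Oregon R and Zimbabwe53 and of St Louis and Zimbabwe53, replicate 2 of Canton S and Hikone R, and those of Zimbabwe2 with Zimbabwe53 or Oregon R and of St Louis and Zimbabwe30.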

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

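The tests of shared labelled cDNA and of a shared slide against the range of means, the test of slides behind the difference between origins, and the share of sides without centring, were chosen after the result had been seen. The other tests in this part were set before.

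Among the 98 groups of 4 strains tested (49 named genes in 2 origins), 6 had a strain far from the other 3, where chance, at about 1 in 20, gives 4.9. The genes were partly named for large strain differences, CG12129 for St Louis among them, so no pattern is read from these. St Louis lay beyond its nearest neighbour by 1.66 log2 (3.15-fold) in CG12129, by 1.21 log2 (2.32-fold) in sphe, by 0.53 log2 (1.44-fold) in cDIP and by 0.34 log2 (1.27-fold) in Glyp. Among Zimbabwe strains, Zimbabwe53 lay apart by 1.20 log2 (2.30-fold) in CG5953, and Zimbabwe29 by 0.76 log2 (1.70-fold) in ocn. On the arrays of a strain against itself, where no difference is expected, 4 features lay beyond 2-fold for Canton S and 10 for Zimbabwe53.

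The Zimbabwe strains stood apart from the other strains in 12 features. Of the 35 splits of the 8 strains, 1 gave as many, the split by origin itself, and the highest other count was 1. This argues against a chance split for this count but does not exclude it, since 1 of 35 is the smallest share possible. The other splits were counted under the main settings only. In features without overlap of the 2 sides, however, 3 of 35 splits reached the 322 of the origin split, the highest with 368. Mismatches between Zimbabwe sequences and the printed DNA would place most differences on 1 side. Of the 540 features with an unadjusted p under 0.05, the larger side held 57.4% (upper 95% limit 61.6%). When arrays were not centred, the opposite side was the larger, with 50.9% of 548 (upper 95% limit 55.2%). Features that reach this p by chance fall on both sides and dilute such a share, and the larger side changed with centring. The shares are therefore only weak evidence against mismatch as the whole cause. For slides shared by arrays, 18 features passed with the title stem as a block, against 12 with each array as a value. The error of this test is the spread between strains, and the block alters only the strain estimates. It therefore cannot decide whether shared slides contribute. A difference between origins remains as a hypothesis, with the reservation that the count fell to 2 when arrays were scaled to 1 spread or print blocks were centred, and to 0 without Zimbabwe2 or Zimbabwe30.

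Arrays that share a title stem deviated together: the correlation of their residuals exceeded that implied by the design in 7 of 8 stems, on average by 0.228. In 3 stems whose arrays had different strains in channel 1, and so no shared labelled cDNA there, the mean excess was 0.284. This was not beyond the upper limit of 0.374 for single pairs of different stems, a bound written before the result was seen that wrongly sets a mean of 3 against single pairs, but it was beyond the upper limit of 0.224 for means of 3 such pairs, chosen afterwards. Also against shared labelled cDNA, the 5 stems that do share the channel 1 strain had a lower mean excess of 0.195, and arrays of different stems with the same channel 1 strain averaged -0.0201. With bounds that disagree and only 3 and 5 stems, shared labelled cDNA and a shared slide still cannot be told apart, and no biological explanation was tested.

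X-linked genes varied less among strains than genes on the large autosomal arms, with a difference of -0.0109 log2 in the median SD. Lower measurement noise on the X is argued against: the median residual SD was 0.177 on the X and 0.175 on the autosomes, and the difference held when X linkage was permuted among genes of like residual SD (permutation p = 0.019). A lower variation of X-linked genes in males remains a hypothesis that these data carry weakly, since leaving out any 1 of 11 arrays raised the p above 0.05.

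The count of 2187 features that differed among strains was set against other assignments of the strain pairs to the arrays. Of 100 assignments, 1 gave as many, the real one, and the highest other gave 18. The count thus depended on which strains the arrays carried. Other assignments also separate arrays that agree, so their low counts say little about noise alone. Chance differences between the single RNA pools of the strains would recur on every array and are not excluded.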

How the results depend on the processing

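Centring by print block, leaving out the last 2 grid rows (for counts beyond 2-fold and single distances too), reducing the testis list and using 1 feature per gene were chosen after the data were seen. No paired analysis was possible because the replicate numbers follow the order of deposition. Title stems do tie arrays of different strain pairs together, and the fit with the stem as a random block is among the alternatives.

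With features complete on all arrays, 1081 features differed among strains, the median over pairs was 322.5 and the calls of strains against the other 7 summed to 2902, against 4938, since fewer features were tested. Leaving out 1 array gave 1754 to 2527 features among strains, 433.5 to 730.5 in the median over pairs and 3596 to 5796 summed calls. The origin count of 12 was 2 with scaled arrays, 2 with centred print blocks, 19 without the last 2 grid rows and 1365 with the error between arrays, which tests the RNA pools and not the origins. It ran from 0 to 58 when 1 array or strain was left out; the cause was not tested. The distance between minus within origins ran from 0.0789 to 0.0865 over arrays left out; its p was at the smallest value that 35 splits allow throughout and so says nothing about stability.

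The X difference was -0.0110 with the title stem as a block, -0.00802 with scaled arrays and -0.00973 without the last 2 grid rows, none past the threshold, and ran from -0.0157 to -0.00751 over arrays left out; the cause was not tested. The ratio of the testis list ran from 2.08 to 2.48, of detoxification enzymes from 1.82 to 2.24 and of muscle genes from 1.10 to 1.38 over arrays left out, each on the same side of the threshold. The ribosomal ratio turned to 0.950 with centred print blocks and ran from 0.986 to 1.23 over arrays left out, never past the threshold. The proteasome ratio was 0.638, past the threshold (adjusted p = 0.046), with 1 feature per gene, and ran from 0.597 to 0.905. List shifts numbered 11 with scaled arrays, 7 with centred print blocks, 6 without the last 2 grid rows, 5 with the estimated correlation and 5 to 9 over arrays left out; the causes were not tested.

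Of 860 values of named genes under the alternatives, 853 kept their call, 7 lost it and 0 reversed. Of 1565 with 1 array left out, 1529 kept their call, 36 lost it and 0 reversed. A range among strains is always positive and has no side, so for ranges only the call was tested. The counts of 0 reversed therefore speak only for values of a strain against the other 7 and of the origins. Whether the extreme strains of a range stayed the same was not tested. Without spot intensities, the part of the noise due to dim spots is unknown.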

Other observations

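The tests of neighbouring genes and of chromosome arms were set before their results were seen, but that a missed threshold leaves both open was decided afterwards; the split of strains seen in the testis genes and the repeated spots were noticed in the data.

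The testis genes janB and ocn were printed 8 and 9 times, and all spots of both passed the F test. The mean over spots differed 2.02-fold between extreme strains in janB and 2.20-fold in ocn, with a median SD between spots of 0.087 and 0.12 log2. In both genes St Louis (0.52 and 0.68 log2 from the mean of the strains) and Zimbabwe29 (0.60 and 0.60) lay on 1 side, with Oregon R (0.27 and 0.43), Zimbabwe30 (0.30 and 0.25) and Zimbabwe53 (0.42 and 0.45) on the other. RpL32, often used as a reference gene, was printed 12 times; 7 of its spots passed, and its mean differed 1.39-fold between extreme strains. The split of the strains with the most features without overlap, 368, set Canton S, Hikone R, St Louis and Zimbabwe29 against the other 4 and so did not follow origin.

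The largest repeated signal has no gene name here. In the last 2 grid rows of the print blocks, 31 of 220 fitted features differed beyond 8-fold, with nearly the same strain profile (median pairwise r = 0.964 across the 8 strains, over spots that are not independent). Hikone R and St Louis lay 1.87 and 1.96 log2 from the mean on 1 side with Oregon R (1.22), and Zimbabwe2, Zimbabwe30 and Zimbabwe53 lay 1.37, 1.61 and 1.81 log2 from it on the other; Canton S (0.18) and Zimbabwe29 (0.080) were near the mean. The last 2 rows made up 4.54% of the features and 26.8% of the summed squared strain deviations.

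Neighbouring genes were tested for shared strain profiles, on the hypothesis that regional differences between strains act on several genes. Over 159 adjacent, non-overlapping pairs the mean correlation across the 8 strains was 0.0660, against a mean of 0.00527 when genes were permuted within arms. It lay below the bound set beforehand, the upper limit of 0.0691 of the permuted means (one-sided permutation p = 0.0313), but so close to it that regional differences are neither shown nor excluded. A second hypothesis held that inversions or introgressed arms concentrate the differing genes of a strain on 1 arm. The largest excess, of Zimbabwe2 on 3L, gave a permutation p of 0.262 over 8 strains and 5 arms, so the threshold set beforehand was not passed and no such arm was detected. That threshold alone was too weak a bound to exclude one: only 21 of 284 genes were called there, 7.39% against 4.60% over all arms, and the exact 95% interval of 4.64% to 11.1% leaves room for more than a doubling.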
